A study of Mus musculus with 6 samples.

How the data were processed

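RNA was sequenced from 6 libraries of primary mouse cells, 3 grown without interleukin-13 (control) and 3 grown with mouse interleukin-13 (IL-13). The cells were selected for the receptor KIT and carried a retrovirus for the W515L form of MPL, and the labels call them megakaryocytes. Each library came as 1 table per sample with expected counts, TPM and FPKM per gene, named per the file headers.

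Per the submitters' processing notes, the authors used Trim Galore 0.60, STAR 2.7 and RSEM 1.31, and the notes name the builds mm10 and GRCh38 without saying what each was used for. The deposited expected counts are RSEM estimates that share reads among genes they fit equally well, and 5.91% to 6.29% of the values per library were not whole numbers. The deposited TPM and FPKM values, per the file headers, are scaled for gene length and library size by the authors. Group means of TPM were tabulated beside the results, FPKM was not used, and no test was run on either. The annotation release and the strand setting of the counting are not given in the sources used here. The gene IDs, symbols and biotypes are those of the deposited tables.

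Expected counts were rounded to whole numbers. The 92 ERCC spike-in sequences had a count of 0 in every library and were left out. Of 55573 genes listed, 15695 were kept by edgeR's filterByExpr by group. The kept genes held 99.9538% to 99.9656% of each library's count. Library totals ranged from 39545600 to 63636600 counts. TMM factors ranged from 0.978 to 1.017. The main test was the robust quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, two-sided, without a term for the replicate number, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are CPM, the rounded counts scaled by edgeR to the TMM-adjusted library total, given as mean ± SD over 3 libraries. Fold changes are IL-13 over control, so a positive log2 value means higher with IL-13.

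The labels do not say that the 3 libraries of a group came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical. Counts of replicates within a group differed by more than sampling noise, with a chi-square per gene of 7.43 to 32.1 where sampling noise alone gives about 1, so no library was treated as a copy of another.

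The design, the comparison, the alternatives and 32 gene lists (pathways, cell type markers and signs of RNA quality) were fixed before the data were examined. Of the 693 symbols on the lists, 687 were in the tables and 617 were tested. Some symbols stand on several lists. A symbol with several IDs was represented by the ID with the highest mean count. Lists were tested, two-sided, with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, with adjustment over the 32 lists. Beside it stand camera with a correlation estimated for each list, fry, and the number of members past the threshold, both over all genes and adjusted over the list alone. Fry asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. Genes named in the text follow a rule. It takes the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold with at least 5 CPM in the higher group and no overlap between groups, the 5 smallest p-values in each direction, the 4 members of each list with the smallest p, and 16 preset genes. Symbols numbered as gene models, Rik symbols and pseudogenes were left out of the parts on largest changes and smallest p. Genes outside it are named as chosen after their values were seen.

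The method was tested on counts simulated for the 15695 kept genes with the measured means and library sizes. Of these genes 200 were changed and a further list of 30 moved together by less. After the filter was applied again, 15514 simulated genes were tested. Among changed genes left after the filter, it recovered 65.7% of 67 changed 1.5-fold, 74.2% of 66 changed 2-fold and 100% of 63 changed 4-fold. Of its 175 calls, 12 (6.86%) were of unchanged genes. Each gene was drawn independently, without shifts shared by the genes of a library, so these rates may be better than in the data. The alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, looser and stricter filters, a minimum fold of 1.5, a term for the replicate number, protein-coding genes only, and leaving out each library in turn. After the data were seen, 3 were added, which were leaving out 2 libraries together, thinning every library to the smallest total, and scaling by library size alone for the lists.

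Coordinates are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, matched by the gene ID with its version. Of the 15695 tested IDs, 15546 matched, and 150 of the 151 named genes did. The exception was Scn3a, for which no coordinates are given. The longest transcript of each named gene was compared with all other transcripts with BLAST 2.17.0, and exon overlap was computed on both strands. Genes with more than 20% of that transcript in alignments of at least 100 bases at 95% identity or more to another gene, or with more than 20% of their exon bases in another gene, are reported as uncertain. Intervals for low counts are 95% intervals and, like the limit of 3 counts that a count of 0 allows, cover counting error only, since reads without molecular identifiers are not independent molecules. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.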

Results

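The data were expression profiles of KIT-positive primary mouse cells transduced with a retrovirus for MPL W515L, an activating mutant of the thrombopoietin receptor found in myeloproliferative neoplasms. The cells were grown for 4 days in StemSpan, a medium for blood stem and progenitor cells, and are labelled megakaryocytes, the cells that release platelets. The 3 control libraries held 47708000, 39545600 and 53223200 counts (to 6 digits), and the 3 libraries with IL-13, a cytokine that signals through the transcription factor STAT6, held 44929000, 60004100 and 63636600. Mitochondrial genes took 2.86% to 3.13% of the counts in control libraries and 3.08% to 3.17% with IL-13. The comparison asked what IL-13 changed in these cells.

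With IL-13, Rnase2a, Retnla and Ccl24, known in myeloid cells as targets of IL-4 and IL-13, rose more than 60-fold by the fit. Of the 31 measured targets 15 did not pass. Of 35 megakaryocyte and platelet genes 16 rose, by smaller amounts, such as Clec1b, and 19 did not pass. Of 21 macrophage and monocyte markers 13 fell, such as Fcgr1 and Lyz2, 1 rose and 7 did not pass. None of these lists passed by camera with a correlation estimated from the data. The adjusted p was 0.47 for the targets, 0.47 for megakaryocyte and platelet genes and 0.54 for macrophage and monocyte markers. Immediate early and dissociation stress genes, read as a sign of handling, also differed, with mean log2 levels relative to the 6 libraries of 0.0997 to 0.120 in the controls and −0.113 to −0.110 with IL-13. In all, 1112 of 15695 genes passed the threshold in edgeR's quasi-likelihood test, 539 higher and 573 lower with IL-13. The median fold was 1.29 among the higher and 1.56 among the lower genes, and 71 higher and 130 lower genes changed at least 2-fold. Values of all 1112 genes separated the 3 control from the 3 IL-13 libraries, as did those of 4873 of all genes (31.0%), where chance gives 10%. With scaling by library size alone 1111 genes passed, 396 higher and 715 lower (35.6% higher, against 48.5% with TMM). The number of calls fell to 249 without IL-13 replicate 2, to 262 without control replicate 2 and to 528 without control replicate 3, and 76 genes passed a test against a minimum change of 1.5-fold.

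Among single genes the largest rise was that of Rnase2a (ENSMUSG00000047222.7), which encodes an eosinophil-associated ribonuclease and lies on chromosome 14 from 51255262 to 51256112 on the minus strand in GRCm38, with 2 exons. Its level went from 0.0429 ± 0.0063 to 8.26 ± 1.15 CPM (counts scaled to library size, mean ± SD, n = 3), a log2 fold change of 7.53 ± 0.24 (SE) with an adjusted p of 2.5e-06 in edgeR's test. Each control library held only 2 of its counts, and the ratio of the groups' summed counts per total was 198, with a 95% counting interval of 90.6 to 539.7. Retnla (ENSMUSG00000061100.4, chromosome 16, 48842551 to 48844461, plus strand, 4 exons), a secreted marker of alternatively activated macrophages, rose from 0.104 ± 0.062 to 6.997 ± 1.539 CPM, with 3 to 7 counts per control library and a ratio of 71.1 (interval 42.2 to 131). Ccl24 (ENSMUSG00000004814.10, chromosome 5, 135569937 to 135573049, minus strand, 3 exons), an eosinophil-attracting chemokine, rose from 1.44 ± 0.84 to 90.5 ± 22.5 CPM, by 6.02 ± 0.43 on the log2 scale (adjusted p = 0.0022). This call was lost when control replicate 3 and IL-13 replicate 1 were left out together (adjusted p = 0.0504). Rbp4, a carrier of retinol, rose by 4.90 ± 0.26 (adjusted p = 1.4e-04), and Cldn11, a tight junction protein, by 4.41 ± 0.34. Chil3 (ENSMUSG00000040809.10, chromosome 3, 106147554 to 106167564, minus strand), a chitinase-like protein, was the most abundant of the 10 largest rises, going from 549.5 ± 116.4 to 4698 ± 457 CPM (log2 fold change 3.10 ± 0.15, adjusted p = 8.8e-05). Scn3a, Tmem26 and St8sia1 rose by 2.65, 2.40 and 2.04, and without those 2 libraries the call of Tmem26 was lost (adjusted p = 0.076). Mgl2, a macrophage lectin, rose by 2.82 ± 0.33 (adjusted p = 0.00998). Its level is uncertain because 43.1% of its longest transcript is shared with Clec10a, and its call was lost without IL-13 replicate 1 (adjusted p = 0.059).

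Among protein-coding genes with at least 5 CPM in the higher group, the largest falls came from Mamdc2 (ENSMUSG00000033207.7, chromosome 19, 23302609 to 23448442, minus strand), which went from 17.2 ± 5.5 to 1.44 ± 0.19 CPM (log2 fold change −3.57 ± 0.27, adjusted p = 7.0e-04), and Fcgr1. Fcgr1 (ENSMUSG00000015947.10, chromosome 3, 96282909 to 96293969, minus strand), the high-affinity IgG receptor of macrophages, fell from 26.7 ± 5.7 to 5.598 ± 0.983 CPM (−2.26 ± 0.18, adjusted p = 7.1e-04). Wfdc17 and Pid1 had log2 fold changes of −2.09 and −2.07, and Gpr162 and Ms4a4c of −1.91 and −1.86. Lpl, the lipoprotein lipase (chromosome 8, 68880491 to 68907448, plus strand), fell from 484.7 ± 47.1 to 141.4 ± 22.9 CPM (−1.78 ± 0.12, adjusted p = 4.0e-04). Dpep2, a dipeptidase, fell by 1.81 ± 0.09 on the log2 scale, although a second gene ID of the same name overlaps 37.3% of its exon bases and its value is therefore uncertain. Cd72 had a log2 fold change of −1.42 and shares 41.6% of its exon bases with Tesk1 on the other strand, which counting without strand would not separate. The acute-phase gene Saa3 had a log2 fold change of −2.09 ± 0.29 (adjusted p = 0.012), and its call was lost without IL-13 replicate 1 (0.072) or IL-13 replicate 3 (0.052). The call was also lost in 3 of the alternatives other than 1 left-out library, among them a minimum change of 1.5-fold (0.074).

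**Figure D1:**
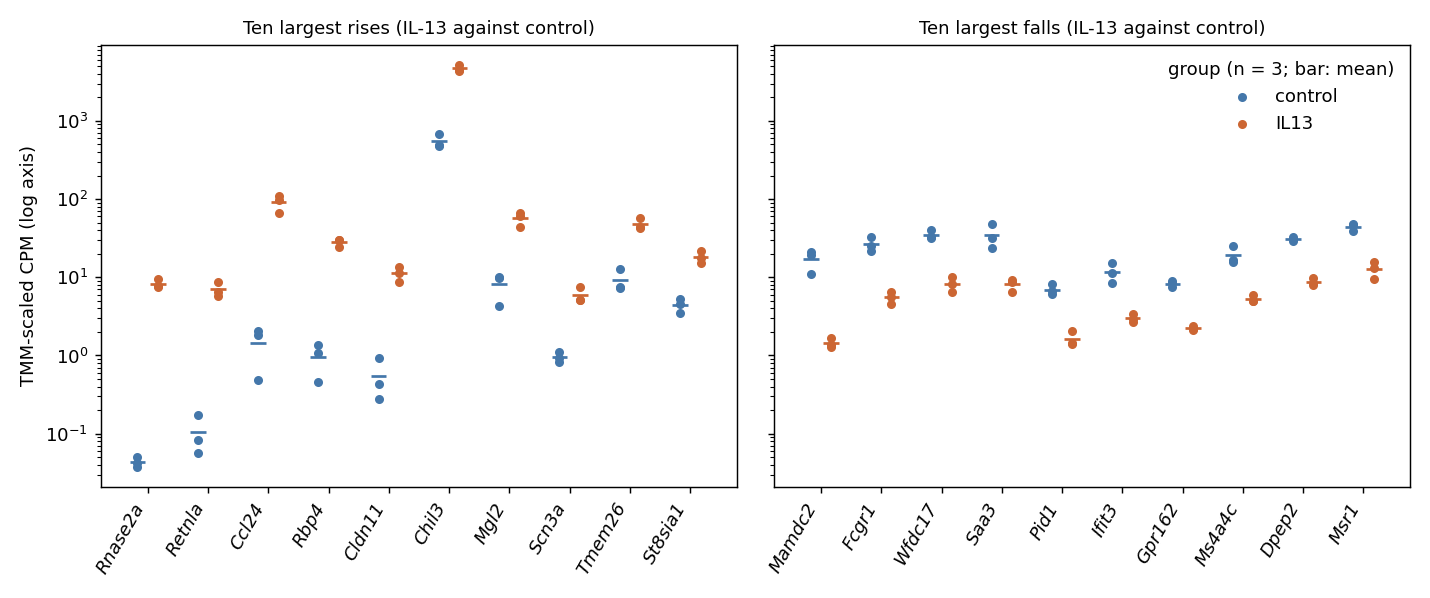
Level of the genes with the 10 largest rises (left) and the 10 largest falls (right) among those with at least 5 CPM in the higher group, in each library, in TMM-scaled CPM on a log axis, for 3 control and 3 IL-13 libraries, with bars at the group means. Rnase2a goes from 0.0429 to 8.26 CPM and Fcgr1 from 26.7 to 5.598, all genes shown having been picked for groups that do not overlap.

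Of the 31 measured IL-4 and IL-13 target genes of myeloid cells, 16 rose, none fell and 15 did not pass (19 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.57. Besides the genes above, Cdh1, which encodes E-cadherin and lies on chromosome 8 from 106603351 to 106670246, rose from 11.6 ± 0.6 to 27.0 ± 1.0 CPM (1.21 ± 0.07, adjusted p = 1.1e-04). Arg1, the arginase that marks alternatively activated macrophages and chosen here after its values were seen, had a log2 fold change of 2.11 ± 0.54 and did not pass (adjusted p = 0.096), with 107.7 ± 58.0 CPM in control and 464.5 ± 99.8 with IL-13. The list was higher by camera (adjusted p = 2.5e-11) but not past the threshold with a correlation estimated from the data (adjusted p = 0.47). Its members at a minimum change of 1.5-fold numbered 8, and its median was 0.33 when control replicate 3 and IL-13 replicate 1 were left out together.

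Components of the IL-4 and IL-13 receptors and of their signalling were read next. Il13ra1, the IL-13 binding chain of the receptor (chromosome X, 36112110 to 36171259, plus strand), fell from 19.4 ± 1.8 to 9.12 ± 1.41 CPM (log2 fold change −1.09 ± 0.12, adjusted p = 0.0019). Il4ra, its partner chain, had a log2 fold change of 0.04 ± 0.07 and Stat6 of −0.01, with adjusted p-values of 0.77 and 0.94. Il2rg, the shared gamma chain, had a log2 fold change of −0.18 (adjusted p = 0.10, and 0.046 without control replicate 3). Gm20489 overlaps 30.5% of the exon bases of Il2rg on the same strand, and its value is uncertain. Il13ra2, the decoy receptor, had 1 count in control replicate 1 and 0 in every other library, where 0 allows up to 3 counts, and was not tested. In the list of 13 receptor and JAK-STAT6 components, Ptpn11 (0.31) and Jak2 (0.22) rose, Il13ra1 fell and 10 did not pass, and the list was not past the threshold (adjusted p = 0.52). Ptpn11 lost its call without control replicate 2 or 3 or IL-13 replicate 2, and Jak2 without any one library but control replicate 1, with adjusted p-values of 0.069 to 0.13. Of 16 genes of cytokine feedback, Cish, a STAT5-induced inhibitor, rose by 0.39 (adjusted p = 0.0065), as did Bcl2l1 by 0.33 and Pim2 by 0.60, while 13 did not pass (8 rose and 1 fell when adjusted over the list alone). That list was higher (camera, adjusted p = 0.023, and 0.54 with an estimated correlation), and its call was lost without IL-13 replicate 1 (0.0501). Only 1 gene of it rose without control replicate 2 or IL-13 replicate 2. Without control replicate 2 and without IL-13 replicate 2 the adjusted p was 0.079 and 0.076 for Bcl2l1 and 0.068 and 0.063 for Pim2, which also lost its call without control replicate 3 (0.078). Mpl had a log2 fold change of 0.24 ± 0.07 (adjusted p = 0.088) and Kit of −0.29 (adjusted p = 0.23), and Mpl passed without IL-13 replicate 3 (0.0076). Reads of a retroviral mouse Mpl would count toward Mpl.

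Among 35 megakaryocyte and platelet genes, 16 rose, none fell and 19 did not pass (30 rose when adjusted over the list alone), and the median log2 fold change was 0.32. Clec1b, a platelet receptor for podoplanin, rose from 148.2 ± 2.8 to 189.1 ± 8.8 CPM (0.35 ± 0.05, adjusted p = 0.0062), and Cd226 by 0.31 ± 0.05 (adjusted p = 0.0085). Itgb3, the beta chain of the fibrinogen receptor (chromosome 11, 104608000 to 104670476, plus strand), rose from 2239.6 ± 184.2 to 3050.4 ± 298.4 CPM (0.45 ± 0.09, adjusted p = 0.021). Pf4, Itga2b and Gp1ba had log2 fold changes of 0.34, 0.36 and 0.31 and did not pass (adjusted p = 0.15, 0.064 and 0.065), but without IL-13 replicate 3 Itga2b and Gp1ba passed (0.019 and 0.011). Of 23 transcription factors of megakaryocytes and erythroid cells, 7 rose and 16 did not pass (9 rose and 1 fell when adjusted over the list alone), among them Fli1, a factor of the megakaryocyte lineage, by 0.50 ± 0.06 (adjusted p = 0.0040) and Mef2c by 0.52 ± 0.08 (0.0080). Gata1 had a log2 fold change of 0.06 (adjusted p = 0.58). Both lists were higher by camera (adjusted p = 1.2e-15 and 6.2e-04), and each had an adjusted p of 0.47 with an estimated correlation. The number of megakaryocyte genes that rose was 3 without control replicate 2, 7 without control replicate 3, 2 without IL-13 replicate 2 and 25 without IL-13 replicate 3, and the median of the list was 0.21 without control replicate 3 and IL-13 replicate 1 together. For the transcription factors it was 2 without control replicate 2 or IL-13 replicate 2 and 3 without control replicate 3 or IL-13 replicate 1. Itgb3 was not past the threshold without control replicate 2 (adjusted p = 0.079), control replicate 3 (0.058) or IL-13 replicate 2 (0.080), and no gene of either list passed at a minimum change of 1.5-fold.

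Fibrosis is a complication of myeloproliferative disease in which megakaryocytes are a source of TGF-beta, and lists of such genes were read for that reason. Tgfb1 (chromosome 7, 25687002 to 25705077, plus strand) was at 651.5 ± 37.3 CPM in control and 746.5 ± 93.2 with IL-13, and did not pass (log2 fold change 0.20 ± 0.09, adjusted p = 0.21). Of 29 genes of TGF-beta signalling, Ltbp1, which holds latent TGF-beta in the matrix, rose by 0.42 ± 0.09 (adjusted p = 0.033), Tgfbi fell by 0.95 ± 0.20 on the log2 scale (0.043), and 27 did not pass (4 rose and 3 fell when adjusted over the list alone). Of 16 collagens only Col5a1 passed (−0.35 ± 0.08, adjusted p = 0.036), while Col1a1 and Col4a1 had log2 fold changes of −0.14 and 0.60 with adjusted p-values of 0.81 and 0.41. Of 20 genes of collagen biosynthesis and cross-linking, Plod2 rose by 0.40. Lox (3.06 ± 0.28 to 1.53 ± 0.45 CPM), Colgalt1, P3h3, Pcolce2 and P4ha2 fell, the last pair being named after their values were seen. When adjusted over the list alone 5 of these 20 genes rose and 7 fell. None of these 3 lists passed (camera, adjusted p = 0.81, 0.37 and 0.49). Leaving out one library ended each of these single calls in 3 or more of the 6 cases for the genes of the naming rule. Without IL-13 replicate 2 the adjusted p was 0.11 for Ltbp1, 0.063 for Tgfbi, 0.14 for Col5a1, 0.096 for Plod2, 0.074 for Lox, 0.11 for Colgalt1 and 0.14 for P3h3, and without control replicate 2 it was 0.10, 0.11, 0.086, 0.10, 0.11, 0.11 and 0.13.

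In the list of 22 matrix proteases and other matrix proteins, 7 genes fell and 1 rose (7 and 3 when adjusted over the list alone). Mmp14, a membrane-bound collagenase, fell from 57.0 ± 2.7 to 34.6 ± 3.5 CPM (−0.72 ± 0.08, adjusted p = 0.0016), and the neutrophil collagenase Mmp8 fell from 106.6 ± 16.9 to 35.3 ± 5.9 CPM (−1.59 ± 0.15, adjusted p = 0.0018). Vcan had a log2 fold change of −0.89 and Spp1 of −0.94. Without control replicate 3 and IL-13 replicate 1 together the adjusted p was 0.0501 for Mmp8 and 0.12 for Spp1. Fn1, fibronectin, was the gene that rose and was named after its values were seen (95.9 ± 31.4 to 228.0 ± 22.9 CPM, 1.252 ± 0.257, adjusted p = 0.044). The list did not pass (adjusted p = 0.094) but did without control replicate 3 (0.015), and 4 of its genes fell without control replicate 2. No gene of the list rose without control replicate 1 or 2 or IL-13 replicate 1 or 2, so that the call of Fn1 was lost there.

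Of 21 macrophage and monocyte markers, 13 fell, 1 rose and 7 did not pass (14 and 1 when adjusted over the list alone), with a median log2 fold change of −0.67. Msr1, a scavenger receptor (chromosome 8, 39581685 to 39642673, minus strand), fell from 44.4 ± 4.6 to 12.7 ± 3.1 CPM (−1.80 ± 0.17, adjusted p = 0.0017). Its call was lost when control replicate 3 and IL-13 replicate 1 were left out together (adjusted p = 0.069), as was that of Clec4n (0.075). Lysozyme, Lyz2, fell from 3727 ± 310 to 1736 ± 231 CPM (−1.10 ± 0.10, adjusted p = 8.9e-04), but 96.0% of its longest transcript is shared with Lyz1 and its level is uncertain. Clec4n had a log2 fold change of −1.30 ± 0.16 (adjusted p = 0.0053). Marco, a scavenger receptor named after its values were seen, was the gene that rose (0.918 ± 0.361 to 3.22 ± 1.22 CPM), and no gene of the list rose without any one library but IL-13 replicate 2. The list was lower by camera (adjusted p = 5.7e-08, and 0.54 with an estimated correlation). The number of markers that fell was 6 without control replicate 2, 7 without IL-13 replicate 2 and 4 without control replicate 3 and IL-13 replicate 1 together, and 3 (Fcgr1, Lyz2 and Msr1) passed at a minimum change of 1.5-fold. Of 22 neutrophil and granulocyte precursor markers 6 fell and 1, Chil3, rose (likewise when adjusted over the list alone). Retnlg fell from 10.03 ± 2.05 to 5.25 ± 0.45 CPM (adjusted p = 0.010, and 0.057 without IL-13 replicate 2). This list did not pass (adjusted p = 0.084) but did without control replicate 1 (0.049), control replicate 3 (0.016) or IL-13 replicate 3 (0.0025), and 2 genes fell without control replicate 2 and 1 without IL-13 replicate 2.

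**Figure D2:**
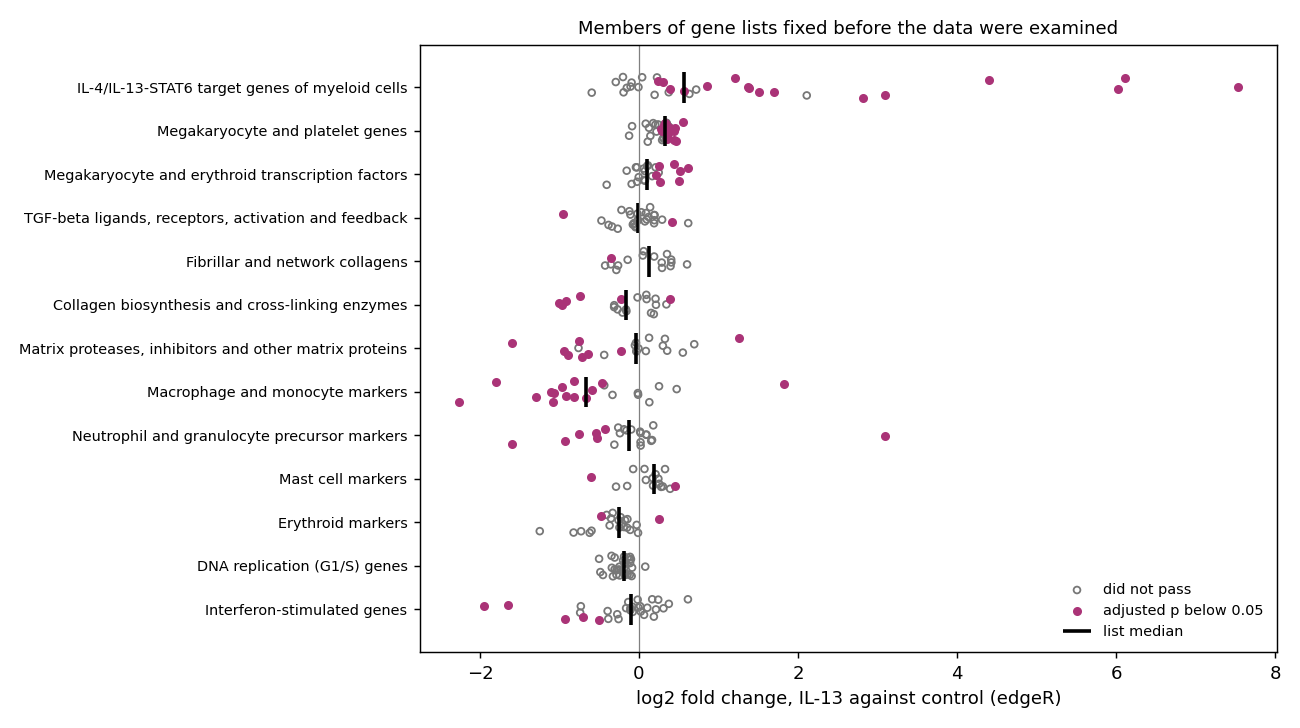
Log2 fold change of IL-13 over control (edgeR) for each measured member of 13 gene lists, filled where the adjusted p was below 0.05, with a bar at the list median. Medians lie at 0.57 for IL-4 and IL-13 target genes, 0.32 for megakaryocyte and platelet genes and −0.67 for macrophage and monocyte markers.

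Of 22 erythroid markers, Gfi1b rose by 0.25 ± 0.06 (adjusted p = 0.047), the globin gene Hba-a1 had a log2 fold change of −0.47 ± 0.12 (0.045), and 20 did not pass (1 rose and 7 fell when adjusted over the list alone). The median was −0.25, and the list was lower by camera (adjusted p = 5.3e-05, and 0.57 with an estimated correlation). Hba-a1 shares 77.0% of its longest transcript with Hba-a2 and its level is uncertain. Genes of DNA replication and of mitosis were lower as lists, with medians of −0.19 over 31 genes and −0.14 over 32 (camera, adjusted p = 4.8e-06 and 3.6e-04, each 0.64 with an estimated correlation). No single gene of either passed, also when adjusted over the list alone, and Ccne1 (cyclin E1), with the smallest p of the first list, had a log2 fold change of −0.45 (adjusted p = 0.064). Control replicate 3 stood apart, with a mean log2 level of erythroid markers of 0.42 relative to the 6 libraries against 0.069 and −0.010 in the other controls, and of DNA replication genes of 0.30 against −0.0052 and 0.025. Without it the medians were −0.16 for erythroid, −0.096 for DNA replication and −0.060 for mitosis genes. Without IL-13 replicate 1 the mitosis list lost its call (median −0.073, adjusted p = 0.0501) and the DNA replication median was −0.12. Without both of these libraries the DNA replication list lost its call (median −0.051, adjusted p = 0.13), and the erythroid median was −0.12. Hba-a1 lost its call without control replicate 1 or any one IL-13 library (adjusted p = 0.072 to 0.14), and Gfi1b without any one library but IL-13 replicate 3 (0.054 to 0.17).

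**Figure D3:**
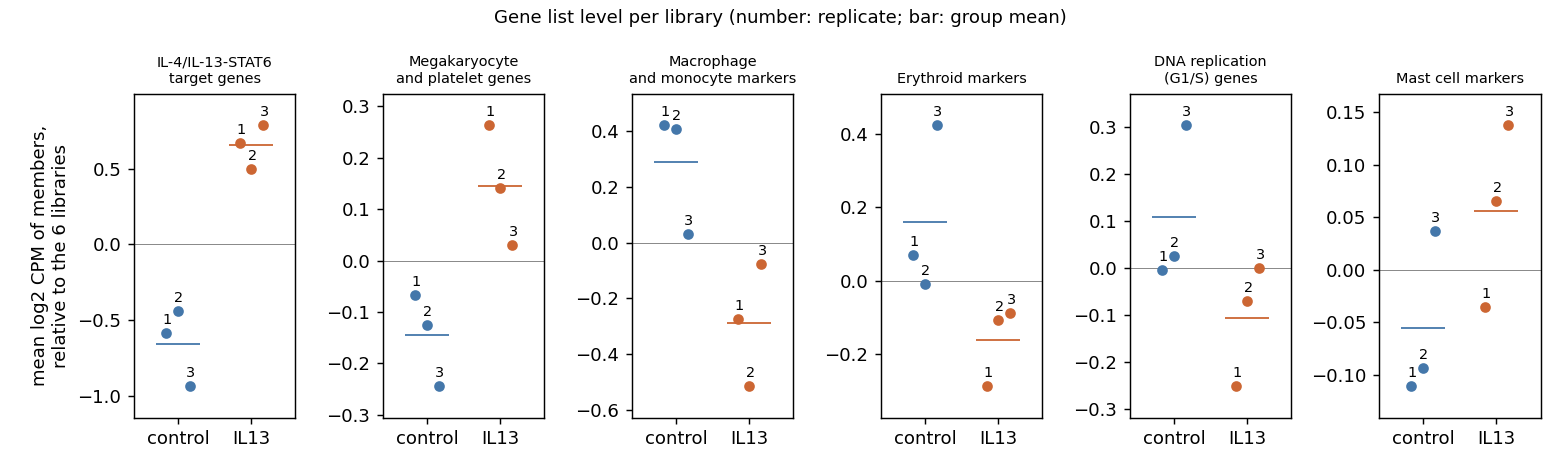
Mean log2 CPM of the members of 6 gene lists in each library, relative to the mean of the 6 libraries, with numbers for the replicate and bars at the group means. For erythroid markers control replicate 3 lies at 0.42 and IL-13 replicate 1 at −0.29.

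In all, 15 of the 32 lists passed by camera with the preset correlation, 9 higher and 6 lower, 0 with an estimated correlation (lowest adjusted p = 0.32, with 2 lists at an unadjusted p below 0.05) and 3 by fry, which were IL-4 and IL-13 targets (adjusted p = 0.039), unfolded protein response genes (0.0094) and immediate early genes (0.0093). A division that put control replicate 1 with IL-13 replicates 1 and 3, against the other libraries, also called 16 lists by camera. Part of the treatment difference remains in that division, so some of its calls may come from treatment. Camera calls alone do not set treatment apart from other differences between these libraries. The lists also share members, so their calls are not separate findings. Batf3, Itgax, Cish, Chil3 and Rnase2a, named under other lists, are also on the list of IL-4 and IL-13 targets. Gfi1b is also on the transcription factor list and Tbxas1 on the megakaryocyte list. The mast cell and basophil lists share Hdc, Fcer1a, Ms4a2 and Gata2. For 6 lists that did not pass, the median, the mean and the test differed in sign. They were mitochondrially encoded genes, IL-4 and IL-13 receptor components, MHC class II, stromal, TGF-beta and eosinophil genes.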

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

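The alternatives added after the data were seen were leaving out control replicate 3 and IL-13 replicate 1 together, thinning to equal depth, and library size alone for lists. Against 1112 genes past the threshold (539 higher, 573 lower), DESeq2 gave 1880 (938 and 942) and the test against a minimum change of 1.5-fold 76 (32 and 44), the latter by its construction, while the cause of the former was not tested. With a term for the replicate number (the block) the counts were 2039, 1023 and 1016, and 18 lists. The eicosanoid (adjusted p = 0.019), neutrophil (0.028) and mast cell (0.039) lists, not past the threshold without it, then passed. With the block 6 named genes lost their calls, among them Mgl2 (0.086) and Spp1 (0.055), and 31 named genes gained one. The numbers share no stated origin, and same-numbered libraries deviated together with correlations of only 0.16, −0.14 and 0.015. Not every library correlated best with its own number, control replicate 3 doing so with IL-13 replicate 2 at 0.20. Leaving out 1 library gave 249 to 1221 genes, 99 to 585 higher and 149 to 636 lower, and 13 to 19 lists, with fewer samples in each fit. Of 15 lists, 0 passed with an estimated correlation and 3 by fry. Among lists with a call in either of the settings compared, the mitosis list alone changed the direction of its test. When 2 libraries were left out together its median was −0.00065 with the direction upward (camera, adjusted p = 0.97). The DNA replication (0.13), cytokine feedback (0.10), p53 target (0.22) and stem cell (0.36) lists lost their calls there. In the same setting 5 lists gained a call, which were the mast cell, matrix (0.0096), inflammatory cytokine (0.016), interferon (0.016) and MHC class II lists. Over all settings the median of a list changed sign in 21 comparisons with no change of call. With the stricter filter the matrix (0.029) and MHC class II (0.012) lists passed. The other settings (RLE, upper-quartile or no scaling factors, limma-voom, no filter, a stricter filter, protein-coding genes, thinning and 2 libraries left out) gave 896 to 1489 genes, within 1.5 times the main count. Of the 97 named genes with a call, 79 kept it in every planned setting other than a minimum fold and a left-out library, and 43 kept it whichever library was left out. The number that lost it was 20, 46 and 32 without control replicate 1, 2 and 3 and 20, 50 and 10 without IL-13 replicate 1, 2 and 3. At these depths Rnase2a (2 counts per control library) and Retnla (3 to 7) have folds known only within their counting intervals.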

Other observations

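Among lists not described so far, 9 of 27 genes of the unfolded protein response and ATF4 pathway rose and 1 fell with IL-13 (12 and 2 when adjusted over the list alone), with a median log2 fold change of 0.12 (camera, adjusted p = 3.6e-04, and 0.32 with an estimated correlation). Vldlr rose by 0.66 ± 0.07 (edgeR, adjusted p = 0.0019). The chaperones Hspa5 and Hsp90b1 rose by 0.34 and 0.31, and Atf3 fell by 0.58 on the log2 scale. The number of these genes that rose was 1 without control replicate 2 or IL-13 replicate 2, 4 without control replicate 3 and 6 without IL-13 replicate 1 or IL-13 replicate 3. Without control replicate 2 the adjusted p was 0.057 for Hspa5, 0.079 for Hsp90b1 and 0.061 for Atf3, and without IL-13 replicate 2 it was 0.053, 0.067 and 0.057. Without control replicate 3 it was 0.052 for Hsp90b1 and 0.0502 for Atf3. Of 19 immediate early and dissociation stress genes, 5 fell and none rose (6 fell when adjusted over the list alone; camera, adjusted p = 8.7e-04, and 0.32 with an estimated correlation). Dusp1 fell by 0.51 ± 0.06 (adjusted p = 0.0020) and Fos by 0.54 ± 0.07 (0.0038). The others were Atf3, Hspa1b, which shares 78.5% of its longest transcript with Hspa1a, and Fosb, named after its values were seen. Hspa1b lost its call without any one library but IL-13 replicate 1 (adjusted p = 0.060 to 0.12), and 2 genes of this list fell without control replicate 2, control replicate 3 or IL-13 replicate 2 and 3 without IL-13 replicate 3. Of 24 cholesterol synthesis genes, Idi1, Mvd and Cyp51 rose and 21 did not pass (5 rose when adjusted over the list alone; camera, adjusted p = 6.2e-04, and 0.54 with an estimated correlation), and 22.6% of the longest transcript of Idi1 is shared with the pseudogene Gm13502. Idi1 lost its call without control replicate 2 (0.070) or IL-13 replicate 2 (0.057), and Mvd and Cyp51 lost theirs without any one library (0.056 to 0.16). Of 17 eicosanoid genes, Pla2g4a (0.43), Tbxas1 (0.45), Alox5 (0.52) and Ptgir (0.37) rose and 13 did not pass (7 rose and 3 fell when adjusted over the list alone; camera, adjusted p = 0.072, and 0.039 with scaling by library size alone). Without control replicate 2 none of these 4 passed (adjusted p = 0.052 to 0.092). Without IL-13 replicate 2 or control replicate 3 only Pla2g4a did, and Alox5 and Ptgir did not without IL-13 replicate 1, nor Ptgir without control replicate 1 (0.071).

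Of the interferon-stimulated genes 5 of 30 fell and none rose (5 fell and 1 rose when adjusted over the list alone), although the list did not pass (camera, adjusted p = 0.18). Ifit3 had a log2 fold change of −1.94 ± 0.21 (edgeR, adjusted p = 0.0018) and Ifit3b of −1.65 ± 0.25 (0.0076), and 97.4% of the longest transcript of Ifit3 is shared with Ifit3b, so their levels are uncertain. The others were Ifit2 (−0.71), Oasl2 (−0.50) and Mx1 (−0.92), Mx1 being named after its values were seen. Control replicate 1 stood apart, with a mean log2 level of these genes of 0.38 relative to the 6 libraries against −0.060 and −0.0074 in the other controls. Without it the list median turned from −0.095 to 0.053 (0.71). The list passed without control replicate 2 (0.0073) or control replicate 3 (0.031), and 3 genes fell without IL-13 replicate 1 and 2 without IL-13 replicate 2. Of 28 inflammatory cytokine genes Il12a rose by 0.59, and Cxcl2, Il18, Lcn2 and, named after its values were seen, Nfkbia fell (3 rose and 7 fell when adjusted over the list alone; camera, adjusted p = 0.11, and 0.014 without control replicate 3). None of these genes passed without control replicate 2 or without IL-13 replicate 2. Of 11 dendritic cell markers Batf3 (1.37), Itgax (0.57) and Fscn1 (1.15) rose and Irf8 fell by 0.60 on the log2 scale (4 and 1 when adjusted over the list alone; camera, adjusted p = 0.10). Batf3 passed whichever library was left out, while Itgax did not without control replicate 3 (0.067) or IL-13 replicate 2 (0.080), Fscn1 not without any one control (0.058 to 0.11), and Irf8 only without control replicate 3 or IL-13 replicate 3. Of 13 eosinophil markers Rnase2a and Ear2 rose (likewise when adjusted over the list alone; camera, adjusted p = 0.82), and 99.7% of the longest transcript of Ear2 is shared with Ear1. Ear2 lost its call when control replicate 3 and IL-13 replicate 1 were left out together (0.11).

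Basophil markers were higher as a list (camera, adjusted p = 0.022, and 0.47 with an estimated correlation), with Cd200r3 (0.51 ± 0.09, edgeR, adjusted p = 0.013) alone among 16 past the threshold, also when adjusted over the list alone. The list lost its call without IL-13 replicate 3 (0.084), and 6 genes rose without control replicate 3 and IL-13 replicate 1 together. Cd200r3 lost its call without control replicate 2 (0.070) or IL-13 replicate 2 (0.064). Of 16 mast cell markers Slc18a2 rose by 0.46 and Mitf fell by 0.60 on the log2 scale (3 and 1 when adjusted over the list alone; camera, adjusted p = 0.084). That list passed without control replicate 3 (0.013), IL-13 replicate 1 (0.019) or both (6.8e-04, median 0.26 against 0.19), and with scaling by library size alone (0.0491). Neither gene passed without control replicate 2 or IL-13 replicate 2. Of 19 stem and progenitor markers 6 rose, among them Angpt1 by 0.55 ± 0.07 (edgeR, adjusted p = 0.0039), and Procr fell (8 and 3 when adjusted over the list alone; camera, adjusted p = 0.047, and 0.64 with an estimated correlation). This list lost its call without control replicate 2 (0.094), control replicate 3 (0.089) or IL-13 replicate 1 (0.14) and with the stricter filter (0.086). The number that rose was 1 without control replicate 2 or IL-13 replicate 2 and 3 without control replicate 3. Procr lost its call without control replicate 1 or 2 or IL-13 replicate 2 (0.060 to 0.086). Apoptosis and p53 targets were higher as a list (0.022, and 0.57 with an estimated correlation, and 0.074 without control replicate 3), with Ccng1 higher and Bcl2l11 lower among 20 (5 and 1 when adjusted over the list alone), and neither passed without control replicate 2 or 3 or IL-13 replicate 1 or 2. Among 14 B-lineage markers Blnk and Il7r fell (3 when adjusted over the list alone; camera, adjusted p = 0.038, and 0.64 with an estimated correlation). Without control replicate 1 the B-lineage list had an adjusted p of 0.28 and without IL-13 replicate 3 of 0.41, thinned to equal depth of 0.086 and with library size alone of 0.063. Neither gene passed without control replicate 2 or 3 or IL-13 replicate 2. Of 11 stromal and endothelial markers Pecam1 rose by 0.59 ± 0.08, Cspg4 had a log2 fold change of −2.39 ± 0.34 and Acta2 of −1.05 (likewise when adjusted over the list alone; camera, adjusted p = 0.81), and Acta2 passed only without IL-13 replicate 3. In the MHC class II list Ctss, a protease, fell by 0.83 ± 0.10 (edgeR, adjusted p = 0.0040) and 14 genes did not pass (1 rose and 6 fell when adjusted over the list alone; camera, adjusted p = 0.53, and 0.032 without control replicate 3, where 5 genes fell). Of 5 T and NK cell markers Cd4 passed, at 65 counts summed over the controls and 30 over the IL-13 libraries (ratio 0.392, interval 0.246 to 0.614), also when adjusted over the list alone, but not without any one library (camera for the list, adjusted p = 0.39). No gene passed in the glycolysis and hypoxia list of 26 (camera, adjusted p = 0.37) or among 15 mitochondrially encoded genes (0.52), also when adjusted over the list alone. Il13 itself, chosen after its values were seen, was at 4.90 ± 2.02 CPM in control and 7.45 ± 1.05 with IL-13 and did not pass (edgeR, adjusted p = 0.23).

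Of the tests below, those on a uniform displacement of other cell types, on a uniform loss of macrophages and on control replicate 3 were chosen after the result was seen. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1112 genes and the highest of the other 9 called 0 (1 split of 10 as large), while for gene lists the real split called 15 and the highest other 16 (2 of 10 as large). Immediate early and dissociation stress genes, listed as a sign of handling, also separated the groups, and whether handling accounts for part of the patterns below was not tested and stays open.

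The first pattern is the higher level of megakaryocyte and platelet genes. With scaling by library size alone the list's median log2 fold change was 0.29 against 0.32 with TMM, which argues against TMM scaling as the cause. Thinning to equal depth left the median at 0.33, which decides nothing about depth, since fold changes are already scaled to library totals, and without control replicate 3 and IL-13 replicate 1 together it was 0.21. If a larger share of megakaryocytes displaced all other cell types alike, the mast cell and macrophage medians would fall by the same amount. They differed by 0.86 (95% bootstrap interval over members 0.43 to 1.20), an interval that leaves out the spread between libraries. The pair was chosen after the result, the mast cell list did not pass (camera, adjusted p = 0.084), and either list may change within its cells. The difference therefore does not decide how cell shares changed. A larger share of megakaryocytes may still account for the pattern, as may higher expression in each megakaryocyte. Both stay open because the libraries hold mixed RNA.

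The second pattern is the lower level of macrophage and monocyte markers. Leaving out any one library kept the median at −0.59 or lower, which argues against one library as the source. The controls did not agree closely, however. The mean log2 level of the list, relative to the 6 libraries, was 0.42, 0.41 and 0.033 in control replicates 1, 2 and 3. In IL-13 replicates 1, 2 and 3 it was −0.27, −0.52 and −0.077, so control replicate 3 lay close to IL-13 replicate 3. Fewer such cells with unchanged expression in each would lower all members alike only if no other cells expressed them. Of 21 members, 14 had a 95% interval that excluded the list's median. These were 7 above it (C1qa, C1qb, C1qc, Cd163, Ly6c2, Mafb and Marco) and 7 below it (Adgre1, Apoe, Cd14, Clec4n, Fcgr1, Lyz2 and Msr1). The intervals assume a normal spread and are too narrow for so few libraries. Other cells in the mixed RNA may express some members, so unequal falls do not decide whether these cells were lost. What lowered these markers stays open.

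The third pattern is the lower level of erythroid and DNA replication genes. Without control replicate 3 the erythroid median was −0.16 (95% bootstrap interval −0.26 to −0.096) against −0.25 with it, and the DNA replication median −0.096 (−0.16 to −0.072) against −0.19. Without IL-13 replicate 1 as well, the medians were −0.12 and −0.051, and the DNA replication list lost its call (camera, adjusted p = 0.13). Both intervals are for control replicate 3 left out alone and include 0.5 times the value with all libraries. They resample genes that move together, with estimated correlations of 0.58 (erythroid) and 0.87 (DNA replication), and leave out the spread between libraries. How much of the pattern rests on that library therefore cannot be told apart from an effect of IL-13 with so few libraries.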
